A study of Homo sapiens with 24 samples.

How the data were processed

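RNA sequencing measured gene expression in 24 libraries of LNCaP cells, a hormone-sensitive prostate cancer line, in 8 groups of 3. Per the labels, the cells carried a lentiviral short hairpin RNA (shRNA) against SIRT1 or a non-targeting control (NTC), were transduced at a multiplicity of infection of 10, selected with 1 µg/ml puromycin and kept as stable knockdown clones in 0.5 µg/ml. The FBS set holds NTC and shSIRT1 cells in fetal bovine serum (FBS). The stripped-serum set holds NTC cells and a SIRT1 knockdown named 10, kept 48 h in FBS medium and 24 h in medium with charcoal-stripped serum (CSS), which removes androgens. These cells then had 24 h of vehicle, 1 nM dihydrotestosterone (DHT, an androgen), or 1 nM DHT with 10 µM enzalutamide, an antiandrogen. The labels do not say whether shSIRT1 and 10 are the same hairpin or clone.

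Per the labels, libraries were made from about 500 ng RNA with a stranded mRNA kit. The authors' steps were CASAVA 1.8.2 and RSEM 1.2.31 on hg19, with the aligner not stated. The deposited files give, for each of 23207 gene symbols, an RSEM expected count, a TPM and an FPKM. The files hold no coordinates and no mitochondrially encoded genes. Expected counts, rounded to whole numbers, were used for every main test. The deposited TPM served 1 alternative test and the marker gene levels, and FPKM was used in no test. The 2 sets carry different kinds of sample labels and differ in the length that RSEM took off each transcript (50 bases in FBS, 224 to 252 in CSS), so they were treated as separate runs and their levels were not tested against each other. A joint fit of the FBS and vehicle libraries served only to compare their knockdown changes.

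Total counts per library were 11.9 to 14.2 M in FBS and 25.2 to 35.1 M in CSS, and the 10 most abundant genes held 4.02 to 5.58% of them. Low counts were removed with filterByExpr by group, which left 14329 genes in the FBS fit, 14558 in the CSS fit of 18 libraries and 15345 in a fit of the 12 FBS and vehicle libraries. At least 99.91% of the counts were kept. TMM factors were 0.992 to 1.005, 0.969 to 1.014 and 0.932 to 1.046, and common biological coefficients of variation 7.83, 7.79 and 7.55%. Genes were tested two-sided with edgeR 4.0.16 quasi-likelihood F tests on R 4.3.3, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. There were 13 comparisons, 12 planned and 1 added, and no adjustment was made across them. Levels in CPM are given as mean ± SD, and folds are those fitted. Where a group had 0 counts, the fold is a lower bound from 3 counts over the group. With 1 to 3 counts, the ratio of counts comes with its exact 95% binomial interval. Such bounds cover counting error only.

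The comparisons, tests, alternatives, rule for naming genes and 33 gene lists (971 symbols, 14 not found in the files) were chosen before the data were examined. The lists cover androgen-induced and androgen-repressed genes, transcriptional cofactors of the androgen response, G1/S, G2/M, homologous recombination repair, MYC and ribosome biogenesis, ribosomal proteins, replication-dependent histones, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation with PGC-1 targets, respiratory chain subunits, polyamine, hypoxia and glycolysis, autophagy and lysosome, sirtuins with NAD metabolism, p53, FOXO, NF-κB, WNT and glucocorticoid targets, interferon-stimulated genes, the unfolded protein response, the integrated stress response, immediate early genes, epithelial, mesenchymal and neuroendocrine genes, 3 lists of markers of other cells (basal cells or other prostate lines, fibroblasts, leukocytes with endothelium), and mitochondrially encoded genes. Each list with at least 5 tested members was tested against the other genes with camera (limma 3.58.1) at the preset correlation of 0.01, adjusted over the lists of a comparison (31 in FBS, 30 in CSS). Camera was also run with the correlation estimated. In the DHT and enzalutamide comparisons against vehicle or DHT, the calls of the androgen-induced, repair, G1/S and G2/M lists held with an estimated correlation. The autophagy call held in 3 of these 4. No other list call did. With the replicate block and an estimated correlation together, the autophagy call held in none of the 4 (adjusted p = 0.0856 and 0.0715 for DHT in NTC and knockdown cells, 0.0983 and 0.0843 for enzalutamide). The repair call was then lost in knockdown cells (0.0715 for DHT, 0.0612 for enzalutamide).

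Named genes follow a fixed rule. SIRT1 is given in every comparison. KLK3, KLK2, TMPRSS2 and FKBP5 are given in every CSS comparison. Some other genes that fall under the rule are not used here. Then come the 8 highest and 8 lowest log2 fold changes (6 and 6 in comparisons of other kinds) among called genes with an average log2 CPM of at least 1 and no overlap between the replicates of the groups, a condition not asked of the interactions. Up to 4 called members with the lowest adjusted p are given for a described list. Fewer may be named, in rank order. By chance, 10% of genes have separated groups of 3 and 3.

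Each comparison was also run with RLE size factors, no low-count filter, a strict filter (at least 1 CPM in 6 libraries, or 3 in FBS), DESeq2 1.42.0, limma-trend on log2(TPM + 1) for genes with a mean TPM of at least 1, the compared libraries alone (CSS) or all 24 (FBS), the replicate number as a block, an absolute log2 fold change of at least 1, and leaving out each library in turn. Chosen after seeing the data were the comparison of the knockdown changes between the sets, fits without the libraries numbered 3 (FBS) or 1 (CSS), FBS libraries 1 and 2 summed, and the block applied to overlaps and lists. No label pairs the replicates. Changes between libraries of the same number correlated across genes at 0.33 to 0.564 over 3 pairs in FBS and 0.161 to 0.75 over 27 in CSS, above the threshold of 0.1 set for reporting a blocked value. Over the 33 pairs of the interactions the range was -0.015 to 0.704, so the lowest lay below that threshold. Blocked values are given there all the same. Nothing says that replicates are separate cultures, so the p-values measure the spread between these samples.

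The tests were tested on simulated data, negative binomial counts with the abundances, depths and dispersions of these fits and 200 genes changed 1.5-fold or 2-fold. EdgeR recovered 59, 64, 73 and 46% of the 1.5-fold changes and 92, 85, 82 and 70% of the 2-fold changes in the FBS knockdown, vehicle knockdown, DHT and DHT interaction designs, and 8.5, 5.7, 6.6 and 2.5% of its calls were unchanged genes. DESeq2 gave 10.3 to 14% such calls. A simulated list of 40 genes raised 1.5-fold was called both ways, and 0 of 30 unchanged lists were. The simulated genes were independent of each other. This therefore does not test calls at the preset correlation where list members vary together. Figures were drawn with matplotlib 3.10.9 on Python 3.11.15. For 1 check, genes were placed on the GRCh38.p14 annotation by symbol, since an hg19 annotation was not used here. Left out were direct tests between FBS and CSS libraries and set tests of lists with fewer than 5 tested members.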

Results

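Gene expression was measured by RNA sequencing in LNCaP prostate cancer cells with a non-targeting hairpin (NTC) or a SIRT1 knockdown, in 8 groups of 3 libraries. The FBS set (NTC, shSIRT1; serum with androgens) had 12.7 to 14.2 and 11.9 to 12.4 M counts per library. The set in charcoal-stripped serum (NTC, knockdown 10) had vehicle, 1 nM DHT, or 1 nM DHT with 10 µM enzalutamide. Its NTC libraries had 28 to 32.3, 29 to 33 and 27.8 to 35.1 M counts, and its knockdown libraries 30.1 to 32.9, 25.2 to 28.1 and 26.4 to 30.4 M. The FBS set asks which genes are SIRT1 targets, and the stripped-serum set asks how SIRT1 acts in the progression of prostate cancer under androgen and antiandrogen. Levels are mean ± SD in counts per M counts, CPM (SD, n = 3 throughout), and adjusted p values are from edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment. Highest and lowest changes are ranked among called genes with an average log2 CPM of at least 1. Outside the interactions, their replicates also do not overlap between groups.

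**Figure D1:**
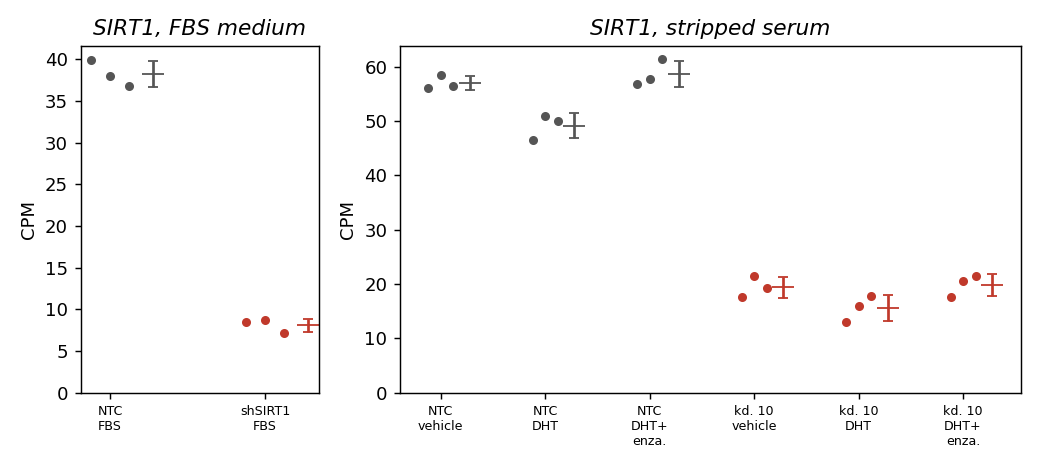
SIRT1 level in CPM in each of the 8 groups; points are libraries and bars are mean ± SD (n = 3).

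In FBS medium, SIRT1, which encodes the deacetylase that the hairpin targets, fell from 38.3 ± 1.6 CPM in NTC to 8.11 ± 0.788 CPM in shSIRT1 cells, 4.71-fold (log2 fold change -2.24, SE 0.093, adjusted p = 8e-06). This comparison asks which genes differ between shSIRT1 and NTC cells in serum that holds androgens. It cannot part SIRT1 loss from a difference between clones. KLK3, which encodes prostate-specific antigen, fell 3.83-fold, from 377 ± 94.5 to 98.5 ± 6.28 CPM (log2 fold change -1.94, adjusted p = 0.000565). The organic cation transporter gene SLC22A3 fell 43.9-fold, from 59.2 ± 4.06 to 1.33 ± 0.592 CPM (adjusted p = 1.44e-06). The gene TOX3 rose 3.77-fold, from 3.86 ± 0.952 to 14.5 ± 0.606 CPM (adjusted p = 0.000565).

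Among the genes so ranked, the highest changes in shSIRT1 cells after TOX3 were in RALYL (log2 fold change 1.24, 5.54 ± 1 to 13 ± 0.795 CPM, adjusted p = 0.00331) and CNTNAP2 (1.23, 8.25 ± 0.315 to 19.3 ± 3.04 CPM, adjusted p = 0.002). The lowest was FCAMR, with 5.39 ± 0.923 CPM in NTC and 0 counts in shSIRT1 cells, at least 65.2-fold lower. H2AFJ fell by a log2 fold change of -5.78 (adjusted p = 0.000565) (16.9 ± 6.25 to 0.299 ± 0.232 CPM), with reads shared with other histone H2A genes not excluded. FAM5C had 4.53 ± 1.78 CPM in NTC and 3 counts in shSIRT1 cells, 56-fold lower (counting interval 18.9 to 274). After SLC22A3 came CBLN2 (-5.37, 6.01 ± 1.35 to 0.137 ± 0.0488 CPM, adjusted p = 0.000141) and KCNH8 (-4.78, 4.76 ± 0.708 to 0.166 ± 0.0871 CPM, adjusted p = 0.000202).

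Over all genes, 389 of 14329 changed in FBS medium: 73 rose and 316 fell. The count was 103, 107, 112 and 115 without shSIRT1 library 1, NTC library 2, shSIRT1 library 2 and NTC library 1, 926 without NTC library 3, and 1676 with the replicate number as a block. It was 164 with limma-trend, 876 with all 24 libraries, 44 with libraries 1 and 2 summed and 3426 without the libraries numbered 3, which leaves libraries 1 and 2, close to each other (chi-square per gene 1.55 in NTC and 1.6 in shSIRT1). Of 55 androgen-induced genes, 1 rose, 10 fell and 44 did not pass (1 rose and 15 fell, adjusted over the list alone), with a median log2 fold change of -0.15. For androgen-induced genes camera gave adjusted p = 2.55e-06, and adjusted p = 0.605 with an estimated correlation. KLK3, NDRG1 (log2 fold change -0.82, adjusted p = 0.00551) and TRPM8 (-1.09, adjusted p = 0.00781) were among those that fell. Of 16 mesenchymal genes, 3 fell and 0 rose (4 and 0, adjusted over the list alone; median -0.38), among them THBS1 (-2.93, 22.1 ± 8.65 to 2.9 ± 0.132 CPM, adjusted p = 0.0025). For mesenchymal genes the camera test gave adjusted p = 5.21e-05, and adjusted p = 0.605 with an estimated correlation. Of 32 hypoxia and glycolysis genes, 3 fell and 0 rose (7 and 0, adjusted over the list alone), with CA12 at -1.26 (adjusted p = 0.00134). For hypoxia and glycolysis genes camera gave adjusted p = 0.0019, and adjusted p = 0.479 with an estimated correlation. With the block, 3 androgen-induced genes rose and 19 fell, and 2 hypoxia and glycolysis genes rose and 8 fell.

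In FBS medium, 0 of 31 integrated stress response genes passed over all genes, while 7 rose and 0 fell, adjusted over the list alone (median 0.23, camera adjusted p = 5.49e-06; adjusted p = 0.665 with an estimated correlation). Of 23 androgen-repressed genes, 2 rose and 2 fell (3 and 3, adjusted over the list alone; median -0.0046). For androgen-repressed genes camera gave adjusted p = 0.27, 0.0422 with the block, and adjusted p = 0.665 with an estimated correlation. Among them PEG3 fell 3.17-fold (522 ± 76.8 to 165 ± 4.54 CPM, adjusted p = 9.52e-05) and ST7 rose (log2 fold change 0.56, adjusted p = 0.00696). RALYL, NDRG1, TRPM8 and ST7 each failed in 1 of the other fits. Without the block, none of the 46 G1/S genes or the 52 G2/M genes passed, over all genes or adjusted over the list alone (G1/S median 0.12, camera adjusted p = 0.0545, 0.000297 with the block, and adjusted p = 0.913 with an estimated correlation; G2/M median 0.10, camera adjusted p = 0.044; adjusted p = 0.913 with an estimated correlation). Histone (2 of 16 fell), repair (0 of 38), interferon-stimulated (3 of 42 fell) and sirtuin genes (1 of 18 fell) also passed camera at the preset correlation (adjusted p = 0.00437, 0.0257, 0.044 and 0.0497, the last 2 at 0.0621 and 0.0787 with the block). They had adjusted p = 0.605, 0.913, 0.911 and 0.615 with an estimated correlation. The block moved the counts over all genes: 18 integrated stress response genes rose and 1 fell, 5 androgen-repressed genes rose and 6 fell, 9 G1/S genes rose and 1 fell, and 5 G2/M genes and 5 repair genes rose. It also gave 8 lower interferon-stimulated genes, and 1 higher and 2 lower sirtuin genes.

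In stripped serum with vehicle, SIRT1 fell from 57 ± 1.3 CPM in NTC to 19.4 ± 1.94 CPM in knockdown 10, 2.93-fold (log2 fold change -1.55, SE 0.093, adjusted p = 2.01e-09). This comparison asks how knockdown 10 cells differ from NTC cells where androgen is low. It cannot part SIRT1 loss from a difference between clones. KLK3 fell 4.23-fold, from 25 ± 2.11 to 5.91 ± 0.93 CPM (adjusted p = 7.09e-08). BIRC5, which encodes survivin, a protein made by dividing cells, fell 3.69-fold (21.9 ± 1.92 to 5.93 ± 1.1 CPM, adjusted p = 4.44e-08), and CDKN1A, which encodes the cell cycle inhibitor p21, rose 2.46-fold (250 ± 21.3 to 615 ± 88.3 CPM, adjusted p = 2.58e-06).

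Among the androgen-regulated genes in vehicle, KLK2 (log2 fold change -1.44, adjusted p = 0.000233), TMPRSS2 (-0.54, adjusted p = 0.00311) and FKBP5 (-0.68, adjusted p = 0.000234) fell in knockdown cells. The highest changes were in CTNNA3 (2.37, 2.12 ± 0.517 to 11 ± 2.73 CPM, adjusted p = 1.74e-06) and GRIN3A (2.26, adjusted p = 3.12e-08). Next came DMGDH (2.15, adjusted p = 6.53e-06), REG4 (1.97, adjusted p = 7.33e-06) and DLX3 (1.81, adjusted p = 4.07e-07). Under the same ranking rule, the lowest were in DDIT4L (-7.88, 11.1 ± 1.9 to 0.0439 ± 0.0504 CPM, adjusted p = 1.55e-10), SLC22A3 (-7.05, 72.7 ± 1.82 to 0.547 ± 0.462 CPM, 132-fold, adjusted p = 9.82e-14) and H2AFJ (-6.99, with the same doubt about shared reads). After these came TLL1 (-6.56, 41.9 ± 10.7 to 0.442 ± 0.161 CPM, adjusted p = 2.75e-09), FCAMR (-6.43), CNTN5 (-6.05, adjusted p = 3.85e-06) and THBS1 (-5.59, 7.96 ± 0.485 to 0.16 ± 0.0537 CPM, 48.3-fold, adjusted p = 2.36e-11).

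Over all genes in vehicle, 5038 of 14558 changed: 2260 rose and 2778 fell, with a median absolute log2 fold change of 0.38. Of 46 G1/S genes, 43 fell, 0 rose and 3 did not pass (43 fell and 1 rose, adjusted over the list alone), median -0.76, among them UHRF1 (-2.11, 18.8 ± 2.04 to 4.36 ± 0.0719 CPM, adjusted p = 4.42e-08), TYMS (-1.17) and FEN1 (-1.07). Camera gave adjusted p = 3.38e-27, and adjusted p = 0.145 with an estimated correlation. Of 52 G2/M genes, 47 fell and 0 rose (48 and 0, adjusted over the list alone), median -1.54, with BIRC5, PTTG1 (-1.51) and NDC80 (-1.84) among them. For G2/M genes the camera test gave adjusted p = 6.98e-42, and adjusted p = 0.145 with an estimated correlation. Of 38 repair genes, 25 fell and 1 rose (26 and 1, adjusted over the list alone), with EXO1 at -2.10 and FANCI at -0.98. For repair genes camera gave adjusted p = 1.46e-08, and adjusted p = 0.291 with an estimated correlation. Of 41 MYC and ribosome biogenesis genes, 33 fell and 0 rose (36 and 0, adjusted over the list alone), and MYC fell from 153 ± 9.87 to 98.3 ± 6.51 CPM (-0.64, adjusted p = 2.68e-05). For MYC and ribosome biogenesis genes camera gave adjusted p = 2.34e-10, and adjusted p = 0.291 with an estimated correlation.

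Of the 55 androgen-induced genes in vehicle, 2 rose and 25 fell (2 and 26, adjusted over the list alone), median -0.37, with KLK3 and KCNN2 (-1.21, adjusted p = 1.06e-07) lower and RHOU (0.53, adjusted p = 1.28e-06) higher. For androgen-induced genes the camera test gave adjusted p = 4.64e-05, and adjusted p = 0.462 with an estimated correlation. Of 24 androgen-repressed genes, 6 rose and 6 fell (8 and 6, adjusted over the list alone); the median was 0.05 while the mean was -0.14 and the test pointed down (camera adjusted p = 0.614). OPRK1 (-2.09, adjusted p = 2.96e-08), DDC (-1.07) and PEG3 (-2.36, adjusted p = 1.17e-06) were among its lower genes. Of 22 fatty acid synthesis genes, 8 fell and 0 rose (8 and 0, adjusted over the list alone), led by FADS1 (82.9 ± 1.99 to 38.1 ± 1.97 CPM, 2.18-fold, adjusted p = 4.33e-09) and FADS2 (2.95-fold, adjusted p = 5.19e-09). For fatty acid synthesis genes camera gave adjusted p = 0.0016, and adjusted p = 0.462 with an estimated correlation. Of 24 epithelial genes, 12 rose and 0 fell (12 and 0, adjusted over the list alone), among them OCLN (0.44, adjusted p = 7.64e-06) and CDH1 (0.45, adjusted p = 1.13e-05). For epithelial genes camera gave adjusted p = 0.000202, and adjusted p = 0.145 with an estimated correlation.

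Of 33 hypoxia and glycolysis genes in vehicle, 19 fell and 3 rose (19 and 3, adjusted over the list alone), with CA12 at -0.95 (adjusted p = 2.71e-09) and HK2 at -1.14. For hypoxia and glycolysis genes the camera test gave adjusted p = 0.000287, and adjusted p = 0.324 with an estimated correlation. Of 31 integrated stress response genes, 14 rose and 2 fell (14 and 2, adjusted over the list alone), with GDF15 2.06-fold higher (adjusted p = 5.11e-05). For stress response genes camera gave adjusted p = 0.000496, and adjusted p = 0.528 with an estimated correlation. Of 49 interferon-stimulated genes, 17 rose and 4 fell (20 and 4, adjusted over the list alone), with HLA-C at 0.68 (adjusted p = 7.54e-06) and PSMB9 at 1.501 (adjusted p = 4.55e-05). For interferon-stimulated genes camera gave adjusted p = 0.00226, and adjusted p = 0.416 with an estimated correlation. Of 38 autophagy and lysosome genes, 14 rose and 0 fell (15 and 0, adjusted over the list alone), with ATG3 at 0.55. With the block, 20 rose and 2 fell. For autophagy and lysosome genes the camera test gave adjusted p = 0.00226, and adjusted p = 0.0796 with an estimated correlation. Of 30 p53 target genes, 8 rose and 3 fell (9 and 3, adjusted over the list alone), CDKN1A among them. For p53 target genes camera gave adjusted p = 0.0532, 0.0318 with the block, and adjusted p = 0.58 with an estimated correlation.

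Under DHT, SIRT1 fell from 49.2 ± 2.34 CPM in NTC to 15.6 ± 2.39 CPM in knockdown cells, 3.14-fold (log2 fold change -1.65, SE 0.095, adjusted p = 8.46e-10). This comparison asks how knockdown cells differ from NTC cells where androgen is present. It cannot part SIRT1 loss from a difference between clones. KLK3 (235 ± 24.3 to 93.1 ± 15.9 CPM, 2.52-fold, adjusted p = 4.52e-07) and KLK2 (-0.85, adjusted p = 0.000488) fell. TMPRSS2 (-0.68, adjusted p = 0.000238) and FKBP5 (-0.73, adjusted p = 6.18e-05) also fell. IGFBP3, which encodes a growth factor binding protein, rose 3.91-fold (91.7 ± 7.99 to 359 ± 33.1 CPM, adjusted p = 1.22e-10). CCNB1, which encodes cyclin B1, fell (log2 fold change -1.55, adjusted p = 7.08e-09).

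The highest changes under DHT were in CTNNA3 (2.76, adjusted p = 5.75e-07), DMGDH (2.28), LOC338651 (2.07, adjusted p = 1.19e-09) and DLX3 (2.03, adjusted p = 2.52e-07). IGFBP3 came next, then REG4 (1.94), PLD1 (1.93, adjusted p = 5.75e-07) and IL1RN (19.9 ± 0.314 to 68.5 ± 1.53 CPM, 3.45-fold, adjusted p = 2.21e-11). The lowest were in H2AFJ (27.8 ± 3.38 CPM to 0 counts, at least 743-fold, shared reads not excluded), FAM65B (-8.92, 26 ± 4.66 to 0.0475 ± 0.0541 CPM, adjusted p = 2.12e-11) and SLC22A3 (59.9 ± 1.71 to 0.172 ± 0.0484 CPM, 337-fold, adjusted p = 1.69e-13). Then came DDIT4L (10.7 ± 1.71 CPM to 3 counts, 287-fold, counting interval 98 to 1400), FCAMR (6.79 ± 0.882 CPM to 2 counts, 275-fold, counting interval 75.7 to 2270) and TLL1 (-7.33, adjusted p = 5.87e-09).

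Over all genes under DHT, 6266 changed: 2840 rose and 3426 fell. All 46 G1/S genes and all 52 G2/M genes fell, over all genes and adjusted over the list alone, with medians of -1.14 and -1.56. RFC4 (-1.09, adjusted p = 2.64e-09) and FEN1 (-1.44) are G1/S examples. Camera gave adjusted p = 6.96e-46 and 1.77e-45, and adjusted p = 0.0795 and adjusted p = 0.0872 with an estimated correlation. Of 38 repair genes, 33 fell and 0 rose (33 and 0, adjusted over the list alone), FANCI among them (-1.32). For repair genes camera gave adjusted p = 2.42e-17, and adjusted p = 0.0872 with an estimated correlation. Of 24 cholesterol synthesis genes, 14 fell and 2 rose (14 and 2, adjusted over the list alone), with FDPS at -0.69 (adjusted p = 6.22e-09). For cholesterol synthesis genes the camera test gave adjusted p = 0.0135, and adjusted p = 0.619 with an estimated correlation. Of 22 fatty acid synthesis genes, 12 fell and 0 rose (12 and 0, adjusted over the list alone), with FADS1 3.23-fold lower (adjusted p = 2.12e-11). For fatty acid synthesis genes camera gave adjusted p = 6.78e-05, and adjusted p = 0.358 with an estimated correlation. Of the 55 androgen-induced genes, 24 fell and 3 rose (24 and 3, adjusted over the list alone; median -0.23, camera adjusted p = 0.00624; adjusted p = 0.619 with an estimated correlation), and 15 of 24 epithelial genes rose while 0 fell (15 and 0, adjusted over the list alone; camera adjusted p = 3.19e-05; adjusted p = 0.0872 with an estimated correlation).

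Under DHT with enzalutamide, SIRT1 fell from 58.7 ± 2.41 to 19.9 ± 2.03 CPM in knockdown cells, 2.95-fold (log2 fold change -1.56, SE 0.093, adjusted p = 1.8e-09). This comparison asks how knockdown cells differ from NTC cells under an antiandrogen. It cannot part SIRT1 loss from a difference between clones. KLK3 (38.7 ± 7 to 12.7 ± 1.81 CPM, 3.05-fold, adjusted p = 4.63e-07), KLK2 (-1.18, adjusted p = 0.000355), TMPRSS2 (-0.48, adjusted p = 0.00663) and FKBP5 (-0.62, adjusted p = 0.000561) fell. The highest changes were in GRIN3A (3.21 ± 0.588 to 18.7 ± 0.776 CPM, 5.81-fold, adjusted p = 5.94e-09), CTNNA3 (2.35, adjusted p = 1.49e-06), DMGDH (2.25), REG4 (1.79) and DLX3 (1.79, adjusted p = 5.38e-07). The lowest were in SLC22A3 (70.1 ± 3.49 to 0.0928 ± 0.0252 CPM, 731-fold, adjusted p = 5.6e-14), DDIT4L (10.8 ± 2.63 CPM to 1 count, 937-fold, counting interval 168 to 37000) and FCAMR (4.92 ± 0.612 CPM to 1 count, 432-fold, counting interval 77.2 to 17100).

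Over all genes under enzalutamide, 5033 changed: 2235 rose and 2798 fell. Of 46 G1/S genes, 40 fell and 0 rose (42 and 0, adjusted over the list alone; median -0.72). For G1/S genes camera gave adjusted p = 2.54e-25, and adjusted p = 0.157 with an estimated correlation. Of 52 G2/M genes, 48 fell and 0 rose, over all genes and adjusted over the list alone (median -1.54), with PTTG1 (-1.64, adjusted p = 9.28e-08) and KIF20A (-2.42) among them. For G2/M genes the camera test gave adjusted p = 1.59e-40, and adjusted p = 0.156 with an estimated correlation. Of the 55 androgen-induced genes, 26 fell and 2 rose (28 and 2, adjusted over the list alone; median -0.33). For androgen-induced genes camera gave adjusted p = 0.000238, and adjusted p = 0.478 with an estimated correlation. Of 24 epithelial genes, 16 rose and 1 fell (16 and 1, adjusted over the list alone). For epithelial genes camera gave adjusted p = 0.000208, and adjusted p = 0.157 with an estimated correlation.

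**Figure D2:**
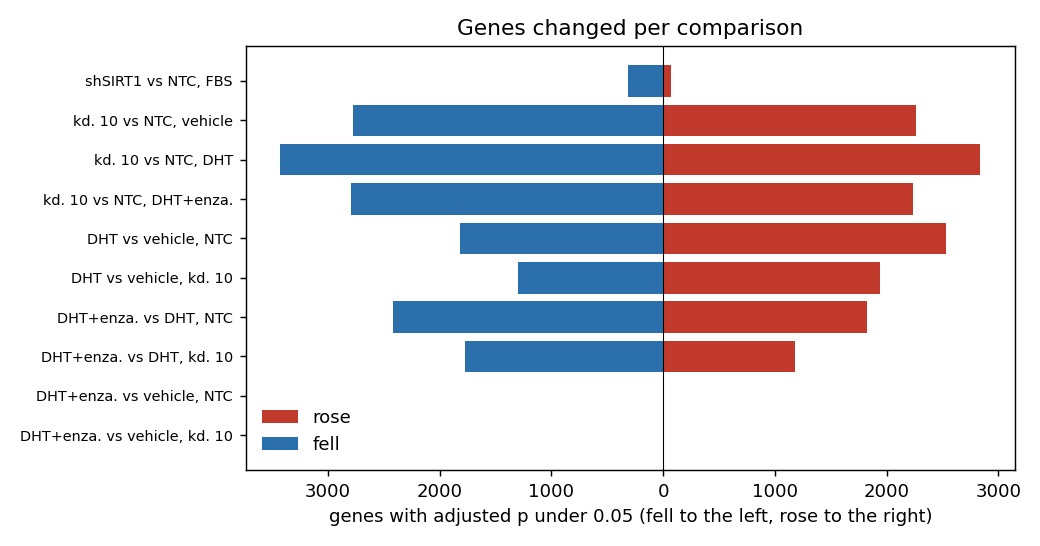
Number of genes with adjusted p below 0.05 in each comparison, higher and lower shown apart (edgeR, 3 libraries per group).

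Of the 13461 genes tested in each, the genes changed in the same direction in all 4 knockdown comparisons numbered 180, 25 higher and 155 lower, against 0.359 and 2.99 from independent lists (677 with the block). SIRT1, KLK3, SLC22A3, DDIT4L, FCAMR, THBS1, KCNH8 and PEG3 were lower in each. PLD1 (log2 fold change 2.31 in FBS, then 1.55, 1.93 and 1.63 in vehicle, DHT and enzalutamide) and TOX3 (1.92, 0.93, 1.44 and 0.93) were higher in each. Between FBS and vehicle, 28 genes rose in both and 174 fell in both (11.4 and 61.6 from independent lists), while 6 and 19 went in opposite directions.

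In NTC cells, DHT left SIRT1 at 49.2 ± 2.34 CPM against 57 ± 1.3 CPM in vehicle, which did not pass (log2 fold change -0.21, adjusted p = 0.0761; 0.00897 with the block). This comparison answers which genes respond to androgen in control cells. KLK3 rose 9.37-fold (25 ± 2.11 to 235 ± 24.3 CPM, adjusted p = 3.96e-10) and KLK2 13.2-fold (6.68 ± 1.52 to 88.3 ± 18.7 CPM, adjusted p = 1.6e-09). TMPRSS2 (2.18-fold, adjusted p = 1.94e-06) and FKBP5 (1.94-fold, adjusted p = 5.2e-06) rose, as textbook androgen-induced genes do. CDK1, which drives entry into mitosis, rose 2.85-fold (119 ± 7.35 to 340 ± 16.7 CPM, adjusted p = 3.36e-08).

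The highest changes with DHT in NTC cells were in TUBA3D (log2 fold change 4.21, adjusted p = 2.39e-07, shared reads with other tubulin genes not excluded), CHRNA2 (3.93, 0.417 ± 0.0592 to 6.42 ± 2.25 CPM, adjusted p = 3.46e-08), KLK2 and KLK3. They were followed by CTNNA2 (3.14, adjusted p = 1.8e-05), F5 (1.52 ± 0.0907 to 12.2 ± 1.15 CPM, 8.05-fold, adjusted p = 1.6e-09), ST6GALNAC1 (2.41 ± 0.554 to 18.7 ± 1.1 CPM, 7.81-fold, adjusted p = 1.6e-09) and ALPK2 (2.94, adjusted p = 3.02e-09). The lowest were in COL5A1 (-1.73, adjusted p = 0.00212) and CNGA1 (-1.67, adjusted p = 8.28e-05). MATN2 was next (-1.61, 7.25 ± 1.17 to 2.38 ± 0.631 CPM, adjusted p = 2.15e-05), then C16orf89 (-1.54), VWA2 (-1.53) and MYOZ1 (-1.53, adjusted p = 1.53e-06).

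Over all genes, DHT changed 4352 in NTC cells: 2529 rose and 1823 fell. Of 55 androgen-induced genes, 46 rose, 1 fell and 8 did not pass (47 and 2, adjusted over the list alone; median 0.84, camera adjusted p = 4.04e-33 and 0.0271 with the correlation estimated). Of 24 androgen-repressed genes, 11 fell and 5 rose (11 and 5, adjusted over the list alone), with DDC (132 ± 1.88 to 62.5 ± 5.23 CPM, 2.11-fold, adjusted p = 4.24e-08) and SLC44A1 (-0.74) lower. For androgen-repressed genes the camera test gave adjusted p = 0.000877, and adjusted p = 0.11 with an estimated correlation. All 46 G1/S and all 52 G2/M genes rose, over all genes and adjusted over the list alone (medians 1.44 and 1.56, camera adjusted p = 4.77e-98 and 1.6e-68, and 0.0107 and 0.0271 with the correlation estimated), with FEN1 (3.18-fold, adjusted p = 1.6e-09), PCNA (1.24) and CKS1B (1.28, adjusted p = 4.19e-09) among them. Of 38 repair genes, 32 rose and 0 fell (33 and 0, adjusted over the list alone; camera adjusted p = 4.1e-36 and 0.0173 with the correlation estimated), BRCA1 among them (3.53-fold, adjusted p = 2.49e-08). Of 24 cholesterol synthesis genes, 20 rose and 1 fell (21 and 1, adjusted over the list alone). For cholesterol synthesis genes camera gave adjusted p = 1.45e-13, and adjusted p = 0.11 with an estimated correlation. Of 22 fatty acid synthesis genes, 14 rose and 0 fell (15 and 0, adjusted over the list alone), with ELOVL5 2.89-fold higher (adjusted p = 2.74e-08). For fatty acid synthesis genes camera gave adjusted p = 6.78e-07, and adjusted p = 0.251 with an estimated correlation. Of 20 FOXO target genes, 8 fell and 0 rose (9 and 1, adjusted over the list alone; camera adjusted p = 0.00505; adjusted p = 0.18 with an estimated correlation), TXNIP among them (-0.58), and with the block 11 fell and 2 rose. In addition, 12 of 38 autophagy and lysosome genes fell while 2 rose (13 and 2, adjusted over the list alone; camera adjusted p = 0.00881 and 0.0362 with the correlation estimated). With the block as well, the autophagy list had adjusted p = 0.0856 with an estimated correlation.

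**Figure D3:**
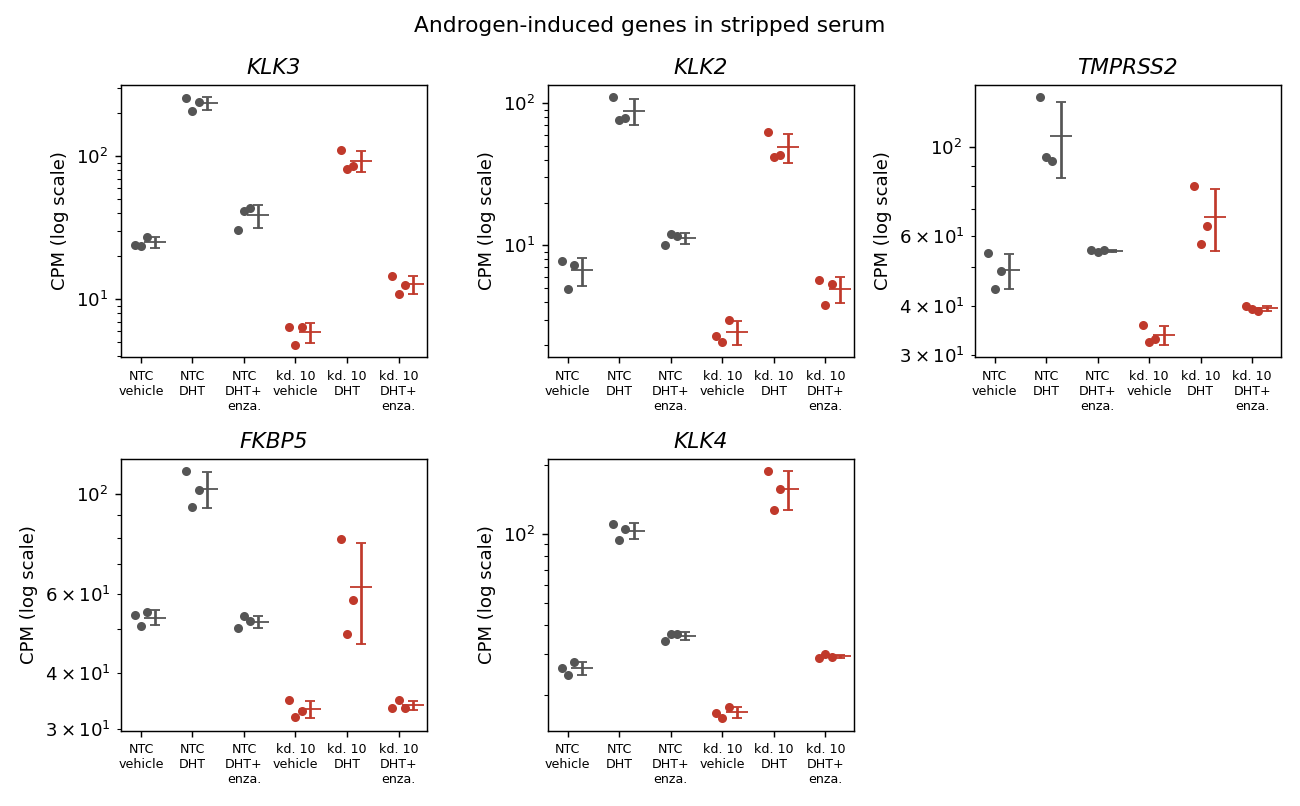
Levels of the androgen-induced genes KLK3, KLK2, TMPRSS2, FKBP5 and KLK4 in CPM on a log axis in the 6 stripped-serum groups; points are libraries, bars mean ± SD (n = 3).

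In knockdown cells, DHT lowered SIRT1 from 19.4 ± 1.94 to 15.6 ± 2.39 CPM (log2 fold change -0.31, adjusted p = 0.0289). This failed without vehicle library 2 (adjusted p = 0.118) or 3 (0.0527), without DHT library 1 (0.119) and with the compared libraries alone (0.111). This comparison answers whether cells with less SIRT1 still respond to androgen. KLK3 rose 15.7-fold (5.91 ± 0.93 to 93.1 ± 15.9 CPM, adjusted p = 4.58e-11), KLK2 19.8-fold (2.48 ± 0.467 to 49.1 ± 11.4 CPM, adjusted p = 8.58e-10) and KLK4 9.39-fold (16.7 ± 0.965 to 157 ± 30.6 CPM, adjusted p = 3.71e-12). TMPRSS2 (0.98, adjusted p = 2.17e-05) and FKBP5 (0.91, adjusted p = 2.32e-05) rose. The highest changes after KLK2 were in CHRNA2 (4.12, 0.278 ± 0.0162 to 4.92 ± 1.7 CPM, adjusted p = 1.57e-07), KLK3, CTNNA2 (3.53), TUBA3D (3.49) and ST6GALNAC1 (1.66 ± 0.339 to 18.7 ± 2.6 CPM, 11.2-fold, adjusted p = 6.54e-10).

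Over all genes, DHT changed 3236 in knockdown cells: 1937 rose and 1299 fell. With the compared libraries alone 1649 passed, and with limma-trend 1106 rose and 1093 fell. Of 55 androgen-induced genes, 43 rose and 0 fell (44 and 0, adjusted over the list alone; median 0.95, camera adjusted p = 1.89e-52 and 0.02 with the correlation estimated). Among 46 G1/S genes, 45 rose and 0 fell (46 and 0, adjusted over the list alone; median 1.09, camera adjusted p = 5.87e-73 and 0.02 with the correlation estimated), with GINS2 3.04-fold higher (5.25 ± 0.486 to 16 ± 1.5 CPM, adjusted p = 4.62e-08). Of 52 G2/M genes, 47 rose and 0 fell (49 and 0, adjusted over the list alone; median 1.51, camera adjusted p = 9.59e-69 and 0.0276 with the correlation estimated), with NDC80 4.18-fold higher (4.44 ± 0.288 to 18.6 ± 1.98 CPM, adjusted p = 1.57e-07). Between NTC and knockdown cells, 1472 genes rose with DHT in both and 830 fell in both (336.5 and 162.7 from independent lists), and 5 and 1 went in opposite directions.

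Enzalutamide added to DHT raised SIRT1 in NTC cells from 49.2 ± 2.34 to 58.7 ± 2.41 CPM (log2 fold change 0.26, adjusted p = 0.0357). This failed without DHT library 1 (adjusted p = 0.13) or 3 (0.063), without enzalutamide library 2 (0.063) or 3 (0.119) and with limma-trend (0.101). This comparison answers which androgen responses the antiandrogen blocks. KLK3 fell 6.06-fold (235 ± 24.3 to 38.7 ± 7 CPM, adjusted p = 8.94e-10) and KLK2 7.88-fold (88.3 ± 18.7 to 11.2 ± 0.987 CPM, adjusted p = 2.88e-09). TMPRSS2 (-0.96, adjusted p = 1.09e-05) and FKBP5 (-0.98, adjusted p = 3.23e-06) also fell. The lowest changes were in TUBA3D (-4.02), CHRNA2 (-3.77, 6.42 ± 2.25 to 0.467 ± 0.0666 CPM, adjusted p = 2.58e-08), ST6GALNAC1 (18.7 ± 1.1 to 1.68 ± 0.232 CPM, 11.1-fold, adjusted p = 8.83e-10) and F5 (-3.00, adjusted p = 8.83e-10). The highest were in MATN2 (2.38 ± 0.631 to 7.47 ± 0.078 CPM, 3.15-fold, adjusted p = 1.46e-05) and DEGS2 (1.63, adjusted p = 0.000407).

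Over all genes, enzalutamide changed 4252 in NTC cells: 1829 rose and 2423 fell. Of 55 androgen-induced genes, 46 fell and 2 rose (47 and 3, adjusted over the list alone; median -0.81, camera adjusted p = 1.84e-27 and 0.0498 with the correlation estimated). All 46 G1/S and all 52 G2/M genes fell, over all genes and adjusted over the list alone (medians -1.54 and -1.93, camera adjusted p = 3.18e-109 and 1.23e-91, and 0.00648 and 0.00957 with the correlation estimated), with FEN1 (-1.75, adjusted p = 8.83e-10) and CKS1B (-1.44, adjusted p = 9.57e-10) among them. In NTC cells 2127 genes rose with DHT and fell with enzalutamide and 1419 fell then rose (420.9 and 229 from independent lists), and 0 went the same way. Both comparisons use the same DHT libraries. In 20 simulations of unchanged groups sharing them, the mean was 0 such genes and the highest 0. No gene was changed in those simulations, so almost none could pass in either comparison. They give no reference for the overlap where DHT has an effect. The 3 DHT libraries cannot be split into parts of at least 2, so part of the excess may come from the shared libraries.

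In knockdown cells, enzalutamide raised SIRT1 from 15.6 ± 2.39 to 19.9 ± 2.03 CPM (log2 fold change 0.35, adjusted p = 0.0176). This failed without DHT library 1 (adjusted p = 0.0772), without enzalutamide library 3 (0.0721) and with the compared libraries alone (0.104). This comparison answers whether cells with less SIRT1 still respond to the antiandrogen. KLK3 fell 7.34-fold (93.1 ± 15.9 to 12.7 ± 1.81 CPM, adjusted p = 1.85e-09) and KLK2 9.94-fold (49.1 ± 11.4 to 4.96 ± 0.998 CPM, adjusted p = 1.24e-08). TMPRSS2 (-0.76, adjusted p = 0.000327) and FKBP5 (-0.88, adjusted p = 3.57e-05) also fell. The lowest changes were in CHRNA2 (4.92 ± 1.7 to 0.28 ± 0.089 CPM, 17.5-fold, adjusted p = 1.23e-07), TUBA3D (-4.04), ST6GALNAC1 (18.7 ± 2.6 to 1.73 ± 0.314 CPM, 10.8-fold, adjusted p = 1.37e-09) and KLK2. Next were AZGP1 (33.8 ± 6.43 to 4.22 ± 0.998 CPM, 8.05-fold, adjusted p = 1.94e-08) and RRM2 (54.4 ± 14.9 to 6.75 ± 0.963 CPM, 8.02-fold, adjusted p = 1.24e-08).

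Over all genes, enzalutamide changed 2949 in knockdown cells (4518 with the block): 1177 rose and 1772 fell. With the compared libraries alone 1550 passed, and with limma-trend 1112 rose and 1007 fell. Of 55 androgen-induced genes, 41 fell and 1 rose (46 and 1, adjusted over the list alone; median -0.87, camera adjusted p = 3.03e-43 and 0.0157 with the correlation estimated). Of 46 G1/S genes 45 fell and of 52 G2/M genes 49 fell, with 0 higher (46 and 51 fell, adjusted over the list alone; medians -1.16 and -1.88, camera adjusted p = 1.64e-86 and 1.3e-100, and 0.0108 for each with the correlation estimated), with NDC80 (-2.58, adjusted p = 2.89e-08) and MKI67 (-2.65) among them. Of 31 integrated stress response genes, 14 rose and 0 fell (21 and 0, adjusted over the list alone; 25 and 0 with the block; median 0.36). For stress response genes the camera test gave adjusted p = 9.87e-08, and adjusted p = 0.345 with an estimated correlation. In knockdown cells 1512 genes rose with DHT and fell with enzalutamide and 900 fell then rose (235.8 and 105 from independent lists; 3666 in all with the block), against a simulated mean of 0.05 and highest of 1, and 0 went the same way. The same limits, from shared DHT libraries and from simulations without any change, hold here.

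**Figure D4:**
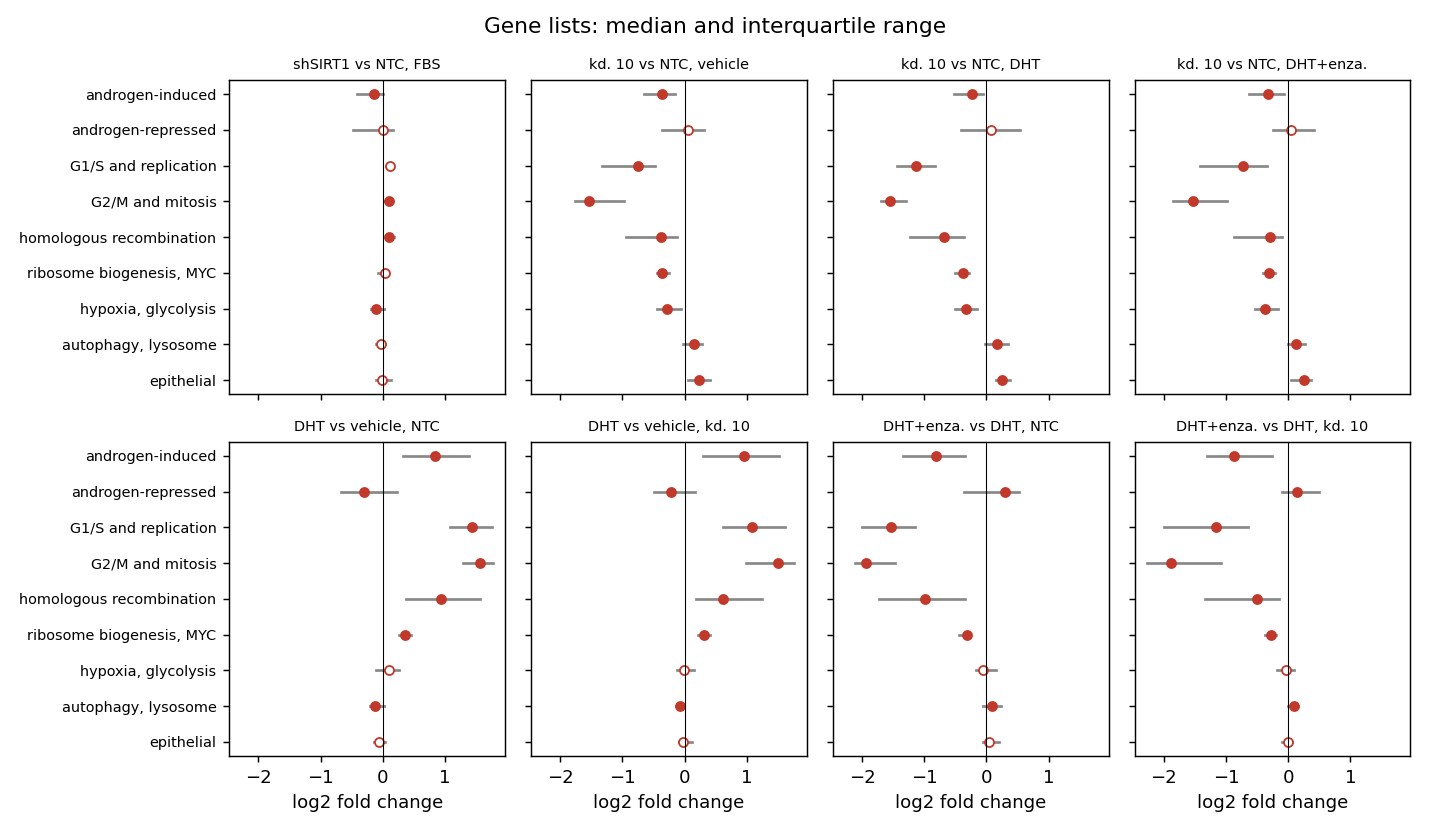
Log2 fold change of the members of 9 gene lists in 8 comparisons; dots are medians, lines interquartile ranges, and filled dots have camera adjusted p below 0.05 at the preset correlation.

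Against vehicle, DHT with enzalutamide gave no SIRT1 difference that passed in NTC cells (log2 fold change 0.04, adjusted p = 1) or in knockdown cells (0.03, adjusted p = 1). These comparisons answer how much androgen response remains under the antiandrogen. In NTC cells 0 genes passed with edgeR (453 with unadjusted p below 0.05), and 0 with DESeq2, limma-trend or the block; 1 passed with the compared libraries alone. KLK3 (0.63), KLK2 (0.74), TMPRSS2 (0.17) and FKBP5 (-0.03) each had adjusted p = 1. In knockdown cells KLK4 rose 1.76-fold, from 16.7 ± 0.965 to 29.4 ± 0.497 CPM (0.81, SE 0.111, adjusted p = 0.0137), the 1 gene that passed of 477 with unadjusted p below 0.05 (5 passed with DESeq2 and 6 with the block). The count was 0 without enzalutamide library 2 or 3 or vehicle library 1 or 3 of the knockdown, and 2 without its enzalutamide library 1. KLK4 failed without vehicle library 1, 2 or 3 (adjusted p = 0.145, 0.0931, 0.0619), without enzalutamide library 2 or 3 (0.0536, 0.0967) and with limma-trend (0.0742). KLK3 did not pass there (1.10, adjusted p = 0.053; 0.0171 with the block), nor did KLK2 (0.99), TMPRSS2 (0.22) or FKBP5 (0.03), each with adjusted p = 1.

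With enzalutamide against vehicle, 0 androgen-induced genes passed in NTC cells (3 rose and 0 fell, adjusted over the list alone; median 0.05, camera adjusted p = 0.00181; adjusted p = 0.698 with an estimated correlation). In knockdown cells 1 rose (4 and 0, adjusted over the list alone; 2 and 0 with the block; median 0.04, camera adjusted p = 2.99e-06; adjusted p = 0.565 with an estimated correlation). The G2/M medians were -0.29 in NTC and -0.31 in knockdown cells, with 0 of 52 genes passing in either (camera adjusted p = 2.6e-33 and 4.36e-28, and 0.253 and 0.565 with an estimated correlation). By library number, the mean log2 CPM of the list was 4.23, 4.53 and 4.51 with vehicle and 3.83, 4.28 and 4.28 with enzalutamide in NTC cells. In knockdown cells it was 3.11, 3.06 and 3.19, and 2.68, 2.81 and 2.92. It was thus lower at each number, though no label pairs the libraries.

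Few single genes passed as differing in their DHT response between knockdown and NTC cells, 29 of 14558 (427 with the block). With edgeR, 1598 had an unadjusted p below 0.05. In simulations this design found 46% of 1.5-fold changes, so more differences may be missed. The DHT response of SIRT1 did not pass as different (-0.10, adjusted p = 0.861). The DHT and enzalutamide interactions ask whether the response to androgen or antiandrogen differs between knockdown and NTC cells. They cannot part SIRT1 loss from a difference between clones. KLK4 rose more with DHT in knockdown cells (16.7 ± 0.965 to 157 ± 30.6 CPM) than in NTC cells (26 ± 1.72 to 103 ± 8.33 CPM; difference in log2 fold change 1.247, SE 0.148, adjusted p = 0.00209). DUT, which supports nucleotide synthesis, went from 49.3 ± 1.66 to 66.7 ± 2.84 CPM in NTC and from 50.4 ± 2.07 to 43.3 ± 2.52 CPM in knockdown cells (-0.65, SE 0.095, adjusted p = 0.00825). KLK3 (0.75, adjusted p = 0.18; 0.0437 with the block), KLK2 (0.59, adjusted p = 0.499), TMPRSS2 (-0.14, adjusted p = 0.848) and FKBP5 (-0.05, adjusted p = 0.955) did not pass.

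Over all genes, the DHT response differed for 29, 6 higher and 23 lower (427 with the block, 156 with DESeq2, 1 with limma-trend, 7 with the compared libraries alone and 14 without the libraries numbered 1). After KLK4, LGALS8 (0.70, adjusted p = 0.0394), C1QTNF6 (0.65) and IL1RN (0.62, SE 0.107, adjusted p = 0.0235) were highest. CCNE2, which encodes cyclin E2, was lowest (-0.80, SE 0.142, adjusted p = 0.0265; 26.4 ± 0.82 to 54.2 ± 3.56 CPM in NTC, 31.4 ± 0.164 to 37 ± 6.74 CPM in knockdown cells), followed by CDT1 (-0.73, adjusted p = 0.0293), DSN1 (-0.66) and PAX9. The count was 5, 6, 7, 9, 9, 10, 16, 16 and 19 without NTC DHT library 3, NTC vehicle library 1, NTC vehicle library 2, knockdown vehicle library 3, NTC vehicle library 3, NTC DHT library 1, knockdown vehicle library 1, NTC DHT library 2 and knockdown DHT library 3. It was 70 and 90 without knockdown DHT library 1 and 2. KLK4 and DUT passed in every leave-one-out fit and failed with limma-trend. LGALS8, C1QTNF6, IL1RN, CCNE2, CDT1, DSN1 and PAX9 failed in 11, 11, 8, 10, 10, 9 and 15 of the other fits. Of the 46 G1/S genes, 5 were lower and 0 higher (21 and 1, adjusted over the list alone; 15 and 0 with the block; median -0.30). For G1/S genes camera gave adjusted p = 2.12e-15, and adjusted p = 0.692 with an estimated correlation. Of 55 androgen-induced genes, 1 was higher and 0 lower (1 and 0, adjusted over the list alone; 3 and 0 with the block; median 0.10). For androgen-induced genes camera gave adjusted p = 0.0535, 0.0447 with the block, and adjusted p = 0.829 with an estimated correlation.

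For the enzalutamide response, SIRT1 did not pass (0.09, adjusted p = 0.86), nor did KLK3 (-0.28, adjusted p = 0.644), KLK2 (-0.34, adjusted p = 0.691), TMPRSS2 (0.20, adjusted p = 0.724) or FKBP5 (0.11, adjusted p = 0.872). The response differed for 51 genes, 39 higher and 12 lower (573 with the block, 254 with DESeq2, 19 with limma-trend and 5 with the compared libraries alone), with CTSL2 (0.93), FANCD2 (0.77), PRIM1 (0.77, adjusted p = 0.00527) and CCNE2 (0.74, adjusted p = 0.033) highest. TMEM45B (-0.98), KLK4 (-0.90, SE 0.144, adjusted p = 0.0102), LOC338651 and IL1RN (-0.73, adjusted p = 0.00527) were lowest. The count was 16, 17, 18, 19, 22, 22, 29, 30, 31 and 33 without NTC DHT library 3, NTC enzalutamide library 1, NTC DHT library 1, knockdown enzalutamide library 2, knockdown enzalutamide library 3, NTC enzalutamide library 2, NTC DHT library 2, knockdown enzalutamide library 1, knockdown DHT library 3 and NTC enzalutamide library 3. It was 104 and 176 without knockdown DHT library 1 and 2. KLK4, IL1RN and PRIM1 passed in every leave-one-out fit, while CTSL2, FANCD2, CCNE2, TMEM45B and LOC338651 failed in 8, 10, 10, 13 and 13 of the other fits. Among 46 G1/S genes, 5 were higher and 0 lower (23 and 1, adjusted over the list alone; 16 and 0 with the block; median 0.34). For G1/S genes the camera test gave adjusted p = 4.11e-16, and adjusted p = 0.543 with an estimated correlation.

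The knockdown change was then compared between stripped serum with vehicle and FBS, a comparison chosen after the data had been seen. SIRT1 fell less in stripped serum, from 58.8 ± 1.48 to 20.6 ± 1.97 CPM, than in FBS, from 36.7 ± 1.59 to 7.78 ± 0.779 CPM (difference in log2 fold change 0.72, SE 0.123, adjusted p = 0.00156). This comparison asks whether the knockdown change differs between the sets, and it cannot part medium from run or hairpin. The difference for KLK3 did not pass (-0.10, adjusted p = 0.833; 362 ± 90.9 to 94.5 ± 6.27 CPM in FBS, 25.8 ± 2.18 to 6.27 ± 1.01 CPM in stripped serum). The knockdown change of KLK2 differed (-1.31, adjusted p = 0.00217): it fell in stripped serum (6.88 ± 1.55 to 2.63 ± 0.499 CPM), and in FBS its change did not pass (167 ± 29 to 157 ± 7.6 CPM, log2 fold change -0.087, adjusted p = 0.739). The knockdown change of CDKN1A differed (1.83, adjusted p = 6.28e-05): it rose in stripped serum, and in FBS its lower level did not pass (203 ± 19.8 to 144 ± 30.5 CPM, log2 fold change -0.49, adjusted p = 0.0955; -0.50 and adjusted p = 0.0142 with the block).

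Between the media, the knockdown change of TMPRSS2 (-0.35, adjusted p = 0.327; -0.39 and adjusted p = 0.0208 with the block) did not pass as different. FKBP5 (-0.83, adjusted p = 0.037) passed, and failed with limma-trend (adjusted p = 0.125). It also failed without NTC FBS library 3 (0.0572), shSIRT1 library 1 or 2 (0.0942, 0.0953), NTC vehicle library 1, 2 or 3 (0.0612, 0.0595, 0.0776) and knockdown vehicle library 2 or 3 (0.0722, 0.0765). Over all genes, 2112 of 15345 differed, 1147 higher and 965 lower in stripped serum (3937 with the block). Of 52 G2/M genes, 46 were lower and 0 higher (47 and 0, adjusted over the list alone; median -1.62), with NEK2 (-1.67, adjusted p = 4.58e-05) and TOP2A (-2.06) among them. For G2/M genes camera gave adjusted p = 1.35e-78, and adjusted p = 0.121 with an estimated correlation. Of 46 G1/S genes, 35 were lower and 0 higher (40 and 0, adjusted over the list alone; median -0.87), with DTL (-2.05, adjusted p = 7.38e-05) and UHRF1 (-2.22) among them. For G1/S genes camera gave adjusted p = 3.78e-36, and adjusted p = 0.192 with an estimated correlation. Of 48 interferon-stimulated genes, 15 were higher and 0 lower (20 and 1, adjusted over the list alone), with HLA-C at 0.89 (adjusted p = 0.000277). For interferon-stimulated genes the camera test gave adjusted p = 2.13e-05, and adjusted p = 0.192 with an estimated correlation. Medium differs between the sets, and the sequencing run is taken to differ from their kinds of labels and RSEM lengths. The labels do not say whether the hairpin differs.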

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

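Of the tests below, the thinning of the vehicle libraries, the placement of genes along the chromosomes, the blocked ratio and the FBS fit without the libraries numbered 3 were run only after the results were seen, and the blocked ratio was also written down only after. These results differed between groups by a test of the difference itself: the 29 and 51 genes whose DHT and enzalutamide responses differed with knockdown, the 2112 genes whose knockdown change differed between media, KLK4 (1.247), IL1RN (0.62) and CCNE2 (-0.80) in the DHT response, the G1/S list median of -0.30 there, and the G2/M list median of -1.62 between media. With an estimated correlation the 2 lists had adjusted p = 0.692 and 0.121. No technical explanation was tested for the 3 genes and 2 list medians.

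The knockdown in vehicle changed 5038 genes, with some lower by more than 100-fold. A lost or gained chromosome segment in a clone could give such a pattern. Against it, 95.4% of the 14558 tested genes were placed by symbol on GRCh38.p14, and after taking off the median of the 20 neighbouring genes 4078 of the 5038 calls were kept (80.9%; 5074 called in all). Of 32 genes at least 16-fold lower, the neighbours had a median log2 fold change of -0.1 (interquartile range -0.44 to 0.13), and 5 had neighbours below -1. SLC22A3 was among these, with neighbours at -1.2, so for it a lost segment stays open. The loss of a single gene would leave its neighbours unmoved, so the neighbours cannot decide on that. In FBS, 17 of these 32 were tested, with a median of -3.26, 14 below -1 and 14 called; whether the hairpin or the clone lowers these genes stays open, since the labels do not say if shSIRT1 and 10 share a hairpin.

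FBS gave 389 calls and vehicle 5038. Lower depth could be the cause, but vehicle libraries thinned to 12.89 M counts still gave 4067 calls (13099 genes tested, biological coefficient of variation 6.68%). A wider spread between FBS replicates could be another cause, but the coefficients of variation differed by a ratio of 1.17, below what was foreseen. With the replicate number as a block, calls were still 3.91 times as many in vehicle. That ratio sets a fit of 18 libraries at full depth against 6 FBS libraries at lower depth. It therefore cannot decide whether spread shared by replicate number plays a part. Without the libraries numbered 3 FBS gave 3426 calls, which rest on libraries 1 and 2, close to each other (chi-square per gene 1.55 and 1.6). Whether these are separate cultures stays open, and with it the spread that the libraries numbered 3 bring, as do medium, run and hairpin.

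In NTC cells 0 genes differed between enzalutamide with DHT and vehicle. Spread shared by replicate number could hide changes, but the blocked count was also 0. The DHT response of the same cells had 4352 calls, so the design could find changes of that size. Changes below the reach of 3 libraries stay open, since the G2/M median was -0.29.

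Labels exchanged between groups of 3 and 3 give 10 splits, too few for a share under 0.05. The real and highest other counts were 389 and 1 in FBS, 5038 and 0 in vehicle, 6266 and 0 under DHT, 5033 and 0 under enzalutamide, 4352 and 0 and 3236 and 0 for DHT in NTC and knockdown, 4252 and 0 and 2949 and 1 for enzalutamide, and 0 and 0 and 1 and 0 for enzalutamide against vehicle. Over 100 splits, the real one included, 8 gave at least the 29 genes of the DHT interaction (highest 5734), 7 at least the 51 of the enzalutamide interaction (highest 5532), and 4 at least the 2112 between media (highest 3128). Every other split that reached these counts exchanged unequal numbers of labels in the 2 arms. Such a split leaves part of the DHT, enzalutamide or knockdown effect in the difference, so these shares do not bear on whether chance gave the 29, 51 and 2112 genes.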

How the results depend on the processing

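Of the alternatives below, those without the libraries numbered 3 or 1, with FBS libraries summed, and the block on overlaps and lists were chosen only after the results were seen. Where a value moved, the cause was not tested. In FBS, 389 calls became 164 with limma-trend on TPM, 876 with all 24 libraries, 3426 without the libraries numbered 3 (all 389 kept with the same sign), 44 with libraries 1 and 2 summed and 108 at an absolute log2 fold change of at least 1. With that threshold the counts were 730, 921 and 766 for the knockdown in vehicle, DHT and enzalutamide, 525 and 364 for DHT in NTC and knockdown cells, 561 and 374 for enzalutamide, 0 for enzalutamide against vehicle in knockdown cells, 1 and 0 for the DHT and enzalutamide interactions and 502 between media, which follows from a stricter rule. The 4-way overlap was 56, and the reversal 433 in NTC and 287 in knockdown cells.

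With the compared libraries alone, counts were 1649 for DHT and 1550 for enzalutamide in knockdown cells, 1 for enzalutamide against vehicle in NTC cells, and 7 and 5 for the interactions. DESeq2 gave 156 and 254 for the interactions and 5 for enzalutamide against vehicle in knockdown cells. Limma-trend gave 1, 19 and 0, the fit with no filter 2 for the last, and the fit without libraries numbered 1 gave 14 for the DHT interaction and 2 for the last. Limma-trend also moved the share of calls that rose with enzalutamide in knockdown cells from 39.9 to 52.5%. For the change between media, TGIF2-C20ORF24, a readthrough with uncertain reads, went from -6.52 to 1.15 without shSIRT1 library 1 and to -8.91 without NTC library 3, and THBS1 to 0.40 with limma-trend.

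The replicate number as a block gave 1676 in FBS (share rising 18.8 to 38.2%), 4518 for enzalutamide in knockdown cells, 6 for enzalutamide against vehicle in knockdown cells, 427 and 573 for the interactions, 3937 between media, 677 genes changed in the same direction in all 4 knockdown comparisons and 3666 for the knockdown reversal. The block also changed list calls: in FBS, interferon-stimulated (0.044 to 0.0621) and sirtuin genes (0.0497 to 0.0787) lost the call and ribosomal proteins gained it (0.164 to 0.0359). Immediate early genes passed under enzalutamide (0.0775 to 0.0407). Interferon-stimulated (0.0374) and p53 genes (0.0474) passed for enzalutamide against vehicle in NTC cells, fatty acid synthesis (0.0472) and mesenchymal genes (0.0114) in knockdown cells, and FOXO targets in the interactions (0.0375 and 0.00765). None of the list calls that the block gained passed with an estimated correlation as well. With an estimated correlation, the block lost the autophagy calls for DHT in NTC cells (0.0856) and in knockdown cells for DHT (0.0715) and enzalutamide (0.0843), and the repair calls in knockdown cells (0.0715 and 0.0612).

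Leaving out 1 library gave 103 to 926 calls in FBS, 4025 to 4622, 5260 to 6379 and 3895 to 4463 for the knockdown in vehicle, DHT and enzalutamide, 3088 to 3974 and 2268 to 3744 for DHT, 3064 to 3875 and 2069 to 3622 for enzalutamide, 0 to 0 and 0 to 2 for enzalutamide against vehicle, 5 to 90 and 16 to 176 for the interactions and 1452 to 2426 between media. The SIRT1 log2 fold change ranged from -2.29 to -2.159 in FBS, -1.62 to -1.47 in vehicle, -1.77 to -1.55 under DHT and -1.62 to -1.47 under enzalutamide. KLK4 lost its call for enzalutamide against vehicle in 5 of 6 such fits. Named genes kept 164 of 264 such calls in FBS, 771 of 798 in vehicle, 84 of 180 in the DHT interaction and 119 of 216 in the enzalutamide interaction. With 11.9 to 14.2 M counts in FBS, changes of 1.5-fold were found in 59% of simulated genes. Small changes in genes of low count may be missed, while large ones were called, as for FCAMR and FAM5C.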

Other observations

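Of the tests below, the deviations of single libraries in list genes were chosen only after the results were seen. In vehicle, several lists showed no common direction that passed with the SIRT1 knockdown, though some of their members passed. Of 66 respiratory chain subunit genes, 0 rose and 6 fell (0 and 5, adjusted over the list alone; median -0.06, camera adjusted p = 0.255), NDUFS6 among them (-0.42). Of 24 PGC-1 and fatty acid oxidation genes, 5 rose and 3 fell (5 and 3, adjusted over the list alone; camera adjusted p = 0.35). Of 20 FOXO target genes, 3 rose and 1 fell (2 and 1, adjusted over the list alone); the median was -0.01, the mean 0.03 and the test pointed up (camera adjusted p = 0.553). Of 18 sirtuin and NAD genes, 3 rose and 4 fell (3 and 4, adjusted over the list alone); the median was 0.03, the mean -0.19 and the test pointed down (camera adjusted p = 0.483), with SIRT2 higher (0.45, adjusted p = 1.67e-06) and PARP2 lower (-0.53). Of 23 transcriptional cofactor genes of the androgen response, 6 rose and 3 fell (6 and 3, adjusted over the list alone; camera adjusted p = 0.35), KDM1A among the lower (-0.45, adjusted p = 5.5e-06). Cholesterol synthesis (2 rose and 5 fell of 24), polyamine (1 and 2 of 11), unfolded protein response (3 and 5 of 20), glucocorticoid (1 and 6 of 16), WNT (1 and 5 of 17), mesenchymal (2 and 2 of 15), histone (7 and 3 of 20) and ribosomal protein genes (0 and 7 of 76) had camera adjusted p of 0.711, 0.595, 0.614, 0.266, 0.262, 0.35, 0.221 and 0.219. With the block, more members passed (rose and fell): respiratory chain 0 and 15, PGC-1 9 and 5, FOXO 6 and 3, cofactors 8 and 6, cholesterol 4 and 7, polyamine 2 and 4, glucocorticoid 3 and 8, and ribosomal proteins 0 and 12.

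In vehicle, 10 of 22 NF-κB target genes rose and 2 fell (10 and 2, adjusted over the list alone; camera adjusted p = 0.0321; adjusted p = 0.416 with an estimated correlation). Of 18 immediate early genes, 6 rose and 1 fell (7 and 1, adjusted over the list alone; camera adjusted p = 0.0187; adjusted p = 0.145 with an estimated correlation), KLF4 among them (1.14, adjusted p = 1.33e-07). Of 11 neuroendocrine genes, 2 rose and 5 fell (2 and 5, adjusted over the list alone; median -0.36, camera adjusted p = 0.0187; adjusted p = 0.145 with an estimated correlation), with SYT4 lowest (-2.50, adjusted p = 9.75e-08).

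Some markers of other cells were near 0, and others were expressed. Markers of basal cells or other prostate lines showed 1 higher and 1 lower of 10 in vehicle (camera adjusted p = 0.692). Mean TPM per group was 9.1 to 34.4 for VIM, 29.65 to 38.51 for MSN and 10.22 to 14.41 for EGFR. It was 0 to 1.27 for KRT14 and 0 to 0.03 for KRT5. Of the fibroblast markers 3 were tested in vehicle (1 higher, 1 lower), with COL1A1 at 3.94 to 7.36 TPM and COL1A2 at 0 to 0.22. Of the leukocyte and endothelial markers 3 were tested (0 higher, 1 lower), with PTPRC at 0 to 0.05 TPM and CDH5 at 0. CD68 had 5.73 to 7.57 TPM and LYZ 1.63 to 9.16. The 13 mitochondrially encoded genes were not analysed here.

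Distances between replicates were uneven. In FBS, libraries 1 and 2 of each group lay close (chi-square per gene 1.55 in NTC and 1.6 in shSIRT1, with 172 and 151 genes apart), while other pairs of replicates had 3.79 to 38.55 (1280 to 6575 genes apart). FBS library 3 deviated from its group mean in G1/S genes (-0.24 in NTC, -0.32 in shSIRT1), G2/M genes (-0.21, -0.3) and integrated stress response genes (0.17 in both). Knockdown DHT library 2 deviated in G1/S (-0.24), G2/M (-0.26) and ribosomal protein genes (0.29), and library 1 of that group the other way (0.22, 0.18 and -0.19). NTC enzalutamide library 1 deviated in G2/M (-0.3), integrated stress response (0.26) and G1/S genes (-0.19). The components held 40.7 and 26.5% of the variance in FBS, the groups and then library 3, and 46.3, 18.7 and 7.5% in stripped serum, the last of which parts the libraries numbered 1. Whether FBS libraries 1 and 2 are separate cultures is not stated.

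The lower G1/S genes and higher CDKN1A with knockdown in stripped serum may reflect slower division of these cells. An alternative is a difference between clones unrelated to SIRT1, which the placement along chromosomes (80.9% of calls kept) does not exclude. A second hairpin, a rescue with SIRT1 and a count of cells over time would part these. In FBS medium the pattern was not seen, though SIRT1 fell further there. Without the block no G1/S gene passed, and with it more rose than fell. There CDKN1A had a log2 fold change of -0.49 (edgeR adjusted p = 0.0955, and -0.50 with adjusted p = 0.0142 with the block). Medium, run and possibly hairpin differ between the sets, so this contrast does not decide between the explanations.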
